A study of Mus musculus with 20 samples.

How the data were processed

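Abdominal skin of 20 mice was profiled, 5 in each combination of genotype (keratinocyte-specific Zfp36 knockout or floxed littermate control) and treatment (imiquimod or mock), per the labels. Total RNA was isolated with Trizol and column purification, and 200 ng were labelled with the Affymetrix WT PLUS kit, per the labels' protocols. The authors deposited 1 table of probe set values for the 20 arrays, with 41345 probe sets each. The deposited values were taken as log2: they run from about 1.41 to 13.33 with 2 decimals, and the scale is read from the values, since the log base is not given in the sources used here. The summarisation, the normalization and the software are not given in the sources used here either; the arrays had nearly equal quartiles (medians 4.94 to 5.04), and genes were not centred. Detection calls were not used here, so it is unknown which probe sets lay above background, and the fold of a dim gene is uncertain.

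Probe sets were named through a table of the array platform. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had no entry; the 17824 probe sets without a single symbol were left out of the gene tests. Symbols were updated through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. Where several probe sets shared a symbol, the one with the highest mean over all arrays stood for the gene (1082 genes), which left 22180 genes. No filter on dim genes was applied. The IL-36 cytokines appear under the symbols Il1f6, Il1f8 and Il1f9.

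Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the deposited log2 values, with 1 mean per group and all 20 arrays in 1 fit (16 residual degrees of freedom, prior degrees of freedom 3.99). The 5 contrasts were imiquimod against mock in each genotype, knockout against control in each treatment, and the difference between the responses of both genotypes. Tests were two-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Zfp36 was also compared with an exact two-sided permutation test in each treatment. A fold is the antilog of a log2 difference and rests on the inferred base.

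In total 25 gene lists were written from background knowledge: stress keratins and small proline-rich proteins, terminal differentiation, basal keratinocytes, antimicrobial proteins and IL-36 cytokines, the IL-23/IL-17 axis, reported ZFP36 targets, NF-kB response, chemokines, type I interferon response, cell cycle, and markers of neutrophils, monocytes and macrophages, T cells, dendritic cells, B and plasma cells, mast cells, fibroblasts, endothelium, adipocytes, skeletal muscle, hair follicle, sebaceous gland, melanocytes, Schwann cells and blood. They had 484 measured memberships of 464 genes, 17 of them in more than 1 list. The list of reported ZFP36 targets shares members with the IL-23/IL-17, NF-kB, chemokine and antimicrobial lists, so calls on these lists are not independent. A further list of sex-linked genes served as a check only. Lists were tested with limma's camera and a preset inter-gene correlation of 0.01, adjusted over the 125 tests of 25 lists in 5 contrasts. Of these, 63 passed with the preset correlation and 12 with a correlation estimated per list, and 25 passed limma's fry, a rotation test of whether a list's genes move one way on balance. The 12 are the 4 lists named with both kinds of p in each of the contrasts of imiquimod in controls, imiquimod in knockouts and genotype under imiquimod.

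Design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups (for the difference in responses, past the threshold only), leaving out provisional symbols and receptor segments. It added the 2 members of each list with the largest rise and the 2 with the largest fall past the threshold, or the 2 with the smallest p where none passed, and Zfp36, Zfp36l1, Zfp36l2, Tnf and Krt14 throughout. The text gives a part of these genes.

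Alternatives were: only the groups of a contrast, the replicate number as a block, a prior variance with an intensity trend or made robust, array weights, quantile normalization or median centring on top of the deposited values, the mean of a gene's probe sets, every probe set by itself, the 30% dimmest genes left out, and hair, muscle, fat or sex-linked genes as a covariate. For lists, an estimated correlation, fry and ranks were used. Each of the 20 arrays was left out in turn. Leaving out the array of each group farthest from its group in hair genes was chosen after seeing the data.

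The fit was tested on simulated data for knockout against control under imiquimod, with 22180 genes of which 200 were changed. It recovered 29 of 67 genes changed by 0.5 on the log2 scale (43.3%), 60 of 67 changed by 1 (89.6%) and 66 of 66 changed by 2, with 15 false calls among 170. The simulated noise was independent between genes and arrays. In the real arrays genes moved together within groups (the first principal component held 45.9% of that variance), so these rates may not carry over. No 2 arrays held identical values. The number of arrays, not a read depth, limits the precision of each value.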

Results

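Gene expression was measured on Affymetrix mouse gene arrays in abdominal skin from mice that lacked Zfp36 in keratinocytes and from control littermates. Zfp36 encodes tristetraprolin, a protein that binds AU-rich elements in messenger RNAs and promotes their decay. The knockout mice carried floxed Zfp36 and a Cre recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes, and the controls carried the floxed gene without Cre. Skin was treated on 5 consecutive days with imiquimod, a Toll-like receptor 7 agonist that produces a psoriasis-like inflammation in mice, or with a mock preparation, and was sampled 4 hours after the last application. Each of the 4 groups held 5 arrays from 5 separate animals, per the series design. The 20 arrays held 41345 probe sets each, with medians between 4.94 and 5.04 on a scale taken as log2, and 22180 genes were tested. The number of arrays limited the precision, with a median standard error of 0.11 for a difference between a pair of groups on the log2 scale. No measure of background was used here, so a fold change from a value near the low end of the scale has an uncertain size. Within groups, arrays correlated between 0.953 and 0.988 across the 41345 probe sets, and arrays of different groups between 0.946 and 0.988.

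Zfp36 itself, the targeted gene, was lower in knockout skin in both treatments, and each knockout array lay below each control array of the same treatment. In mock-treated skin its log2 value was 7.46 ± 0.22 in controls and 5.43 ± 1.54 in knockouts (SD, n = 5 each), a 4.08-fold lower level, with an exact two-sided permutation p = 0.00794. In imiquimod-treated skin it was 8.0 ± 0.26 in controls and 6.40 ± 0.85 in knockouts (SD, n = 5 each), a 3.03-fold lower level, with the same exact two-sided permutation p, the smallest that 5 arrays against 5 can give. In the test over all genes Zfp36 did not pass (adjusted p = 0.999 in mock, 0.221 in imiquimod). The knockout values spread widely, from 3.47 to 7.12 in mock-treated and from 5.47 to 7.41 in imiquimod-treated skin. Zfp36 was read by 1 probe set (17488458). Whether its probes lie within the floxed part is not given in the sources used here, and skin cells other than keratinocytes keep the gene. The related Zfp36l1, which encodes another AU-rich element binding protein, did not pass the test between genotypes in imiquimod-treated skin (log2 difference 0.20, adjusted p = 0.342).

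The first comparison asked what imiquimod changed in skin with intact Zfp36. Genes of the stressed and cornifying epidermis rose most. Serpinb3a, a serine protease inhibitor of squamous epithelium, rose 75.4-fold (log2 difference 6.24 ± 0.33, SE, n = 5 per group, adjusted p = 1.87e-10). Krt6b, a keratin of activated keratinocytes, rose 35.5-fold, from a log2 value of 5.38 ± 0.66 to 10.53 ± 0.89 (SD, n = 5 each, adjusted p = 1.43e-08). Il1f6, which encodes the inflammatory cytokine IL-36 alpha, rose 27.1-fold (adjusted p = 1.16e-09), and Defb3, an antimicrobial beta-defensin, rose 20-fold (adjusted p = 3.3e-08). Retnla, a product of alternatively activated macrophages and fat tissue, fell by 3.14 ± 0.46 on the log2 scale (SE, n = 5 per group, adjusted p = 0.000104). In all, 1435 genes rose and 969 fell in control mice, of which 347 and 99 changed at least 2-fold.

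Basal keratinocyte genes moved both ways, with 3 of 12 higher and 1 lower (3 and 2 adjusted over the list alone; list adjusted p = 0.555): Krt14, the basal keratin, rose by 0.85 ± 0.12 (SE, n = 5 per group, adjusted p = 8e-05) and Krt15, a keratin of follicle stem cells, fell by 1.16 (adjusted p = 0.0131).

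By group, 20 of the 25 measured stress keratins, small proline-rich proteins and stefins rose in control mice, or 21 adjusted over the list alone, with a median log2 difference of 3.59. Lce3e, a late cornified envelope gene, rose 36.9-fold and Sprr1b, a cornified envelope precursor, by 4.41 on the log2 scale. Of 20 antimicrobial and IL-36 genes 14 rose (15 rose and 1 fell adjusted over the list alone), with a median of 1.91. The terminal differentiation list had 28 of 34 members higher and 1 lower, the keratin gene Krt77 (30 and 1 adjusted over the list alone), among them Rptn, encoding the envelope protein repetin, 21.2-fold higher. Of 21 genes of the IL-23/IL-17 axis, a cytokine circuit of psoriatic inflammation, 6 rose (8 adjusted over the list alone), including the chemokine gene Ccl20 (log2 difference 1.65, adjusted p = 3.2e-08) and the cytokine gene Il20 (1.06, adjusted p = 0.000231). Krt77 lost its call without control imiquimod replicate 3 (adjusted p = 0.0503). These 4 lists passed the list test both with a preset correlation (adjusted p = 8.39e-35, 1.62e-20, 2.65e-26 and 9.96e-06) and with an estimated one (0.0053, 0.00782, 0.0385 and 0.0385).

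Among reported targets of ZFP36, 8 of 30 rose in control mice (10 adjusted over the list alone), led by the cytokine gene Il1a at 7.47-fold and by Ier3, an immediate early response gene. That list passed the preset test (adjusted p = 1.31e-05) and not the other (adjusted p = 0.168 with an estimated correlation). Tnf, the best known ZFP36 target, did not pass (log2 difference 0.35, adjusted p = 0.136). Of 18 NF-kB response genes 6 rose, including Nfkbiz, a regulator of NF-kB target genes, by 1.22 (6 also adjusted over the list alone; preset adjusted p = 0.00175; adjusted p = 0.504 with an estimated correlation). Chemokines moved both ways: 6 of 31 rose, among them Cxcl13, which attracts B cells, by 2.78, and 4 fell, among them Cxcl14, a chemokine made in resting epithelium, at -1.45 (the same numbers adjusted over the list alone; list adjusted p = 0.647). No member of the 27-gene type I interferon list passed in limma, and the list's median was 0.01 (adjusted p = 0.919). Cell cycle genes had 3 of 33 higher, over all genes and adjusted over the list alone, with the replication licensing gene Mcm4 at 0.71 (preset adjusted p = 0.000801; adjusted p = 0.758 with an estimated correlation). Mcm3, another of these 3, lost its call without control mock replicate 3 (adjusted p = 0.058). Without control mock replicate 5 the preset call on the cell cycle list was lost (adjusted p = 0.0808).

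Other tissue compartments changed in control skin as well. Fibroblast and matrix genes had 7 of 19 lower (11 adjusted over the list alone), with Fn1, encoding fibronectin, at -1.10 and Col1a1, a type I collagen chain, at -1.06 (preset adjusted p = 4.27e-05; adjusted p = 0.504 with an estimated correlation). Sebaceous gland genes had 8 of 19 higher and 1 lower, the desaturase gene Scd3 (11 and 3 adjusted over the list alone), with Awat1, a wax ester synthase, at 2.62 and Elovl3, a fatty acid elongase, at 2.47 (preset adjusted p = 4.27e-05; adjusted p = 0.276 with an estimated correlation). Scd3 lost its call without control mock replicate 3 or control imiquimod replicate 1 (adjusted p = 0.068 and 0.063). Of 19 monocyte and macrophage markers 5 rose and 1 fell (7 and 2 adjusted over the list alone). Adgre1, encoding the macrophage marker F4/80, rose by 1.75, and Arg1, encoding arginase, fell by 1.05 ± 0.13 (SE, n = 5 per group, adjusted p = 1.67e-05). The list's median was 0.39 (preset adjusted p = 0.0364; adjusted p = 0.753 with an estimated correlation), and its preset call was lost without control mock replicate 1, 2 or 4 (adjusted p = 0.17, 0.103 and 0.0908) and without control imiquimod replicate 1, 2 or 4 (adjusted p = 0.0973, 0.0921 and 0.059). With the hair list as a covariate its median was -0.041. Of 20 neutrophil markers 2 rose, over all genes and adjusted over the list alone, among them the chemokine receptor gene Cxcr2 at 2.03 (list adjusted p = 0.149).

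Hair shaft and follicle genes varied widely within groups. In mock-treated controls the mean log2 value of this list was 5.87 in replicate 5 against 9.13 to 10.06 in the other arrays, and in imiquimod-treated controls it was 9.16 in replicate 5 against 5.28 to 5.88. The knockout groups were spread more evenly: mock replicates 3 and 2 lay at 5.82 and 7.82 against 9.57 to 10.01 in the other arrays, and imiquimod replicates 1 and 4 at 8.96 and 7.27 against 5.51 to 5.80. The list had a median log2 difference of -2.94 with imiquimod in controls, and 0 of its 29 members passed limma over all genes, with 5300 of 22180 genes at an unadjusted p under 0.05; 27 were lower adjusted over the list alone (preset adjusted p = 4.41e-10; adjusted p = 0.482 with an estimated correlation). The hair keratin gene Krt81 lay at -2.62 (adjusted p = 0.054). Melanocyte genes, with 1 of 10 lower over all genes and adjusted over the list alone, had a median of -0.86 (preset adjusted p = 0.00172; adjusted p = 0.514 with an estimated correlation), and Mitf, the master regulator of melanocytes, fell by 1.10. Without the array of each group farthest from its group in hair genes, an alternative chosen after seeing the data, imiquimod changed 3583 genes in control mice.

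**Figure D1:**
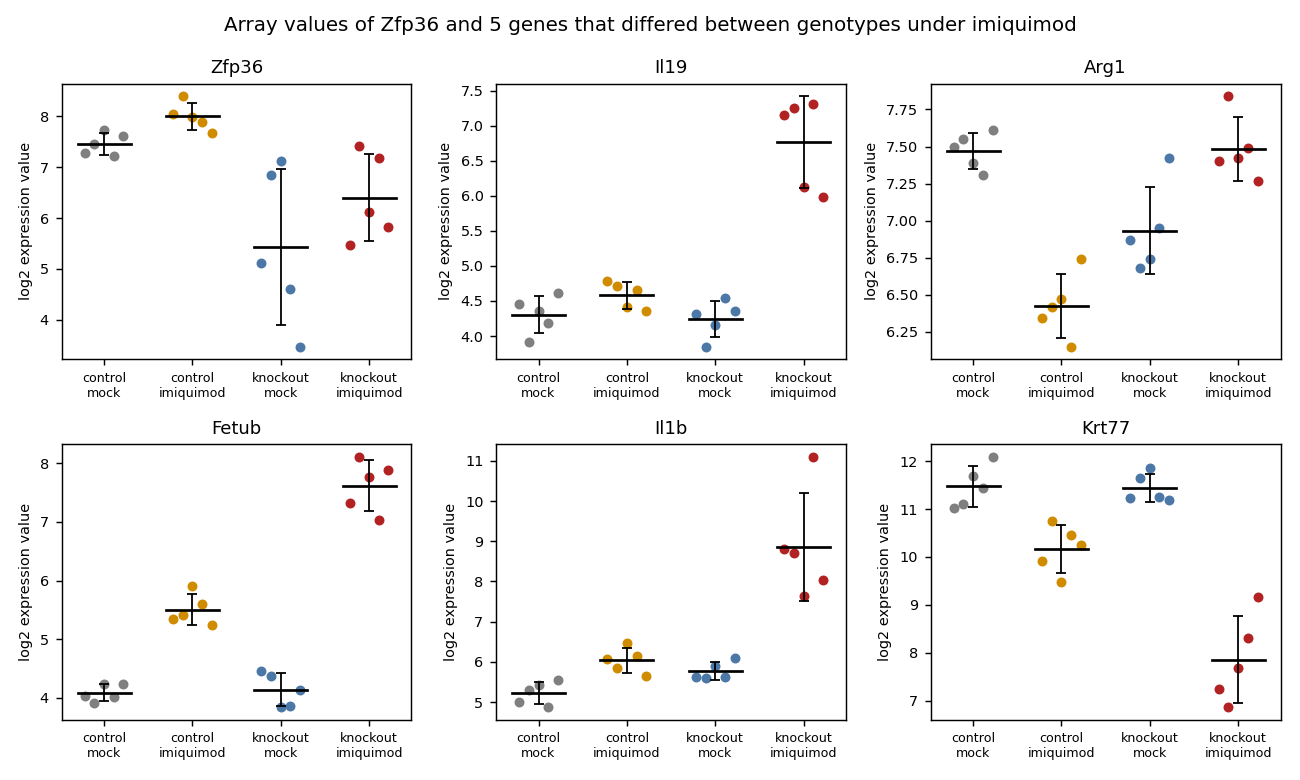
Log2 values (vertical axis) of named genes in each of the 20 arrays, with the mean and SD of each group of 5. Zfp36 lies lower in knockout than in control arrays of either treatment, and Il19 lies at 4.58 in imiquimod-treated controls against 6.77 in imiquimod-treated knockouts.

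The same treatment was compared in knockout skin. The cystatin gene Csta3, a cysteine protease inhibitor of the stefin family, rose 149-fold (log2 difference 7.22 ± 0.45, SE, n = 5 per group, adjusted p = 7.88e-10). Defb3 rose 60.4-fold (adjusted p = 3.02e-10), Sprr2e, a small proline-rich protein gene, 57.5-fold (adjusted p = 4.63e-11), and S100a8, which encodes a subunit of calprotectin, 49.1-fold (adjusted p = 3.16e-08). The cytokine gene Il1b rose 8.54-fold (log2 difference 3.09 ± 0.41, SE, n = 5 per group, adjusted p = 1.54e-05). Krt77, a keratin of suprabasal epidermis, was 12-fold lower (log2 difference -3.59 ± 0.33, SE, n = 5 per group, adjusted p = 2.09e-07), and Retnla was 31.6-fold lower (adjusted p = 2.32e-07). In all, 2451 genes rose and 2154 fell, of which 443 and 225 changed at least 2-fold. Members of the Sprr2, stefin, Lce3, Serpinb3 and Skint families are close in sequence, and their probe sets may share signal.

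The stress keratin group had 21 of 25 members higher in knockout skin (23 adjusted over the list alone, median 4.16), and the antimicrobial and IL-36 group had 18 of 20 higher over all genes and adjusted over the list alone (median 2.90), among them the acute-phase gene Saa3 at 5.51. Of the IL-23/IL-17 axis 13 of 21 rose (15 adjusted over the list alone), with Il19, a cytokine of the IL-10 family, at 2.53. Reported ZFP36 targets had 18 of 30 higher (20 adjusted over the list alone), including Ccl3, a chemokine for monocytes and neutrophils, at 2.75, and Tnf at 0.98 ± 0.14 (SE, n = 5 per group, adjusted p = 5.79e-05). These 4 lists passed with the preset correlation (adjusted p = 8.16e-35, 6.65e-26, 1.57e-09 and 9.87e-12) and with an estimated one (0.0053, 0.0053, 0.00782 and 0.0244). The terminal differentiation list had 22 of 34 higher and 3 lower (26 and 3 adjusted over the list alone), with Rptn at 3.93 and Lce1m, another late cornified envelope gene, at -2.37 (preset adjusted p = 1.02e-11; adjusted p = 0.22 with an estimated correlation).

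Further groups passed camera in knockout skin with the preset correlation and not with an estimated one. In fry the cell cycle, NF-kB, neutrophil and dendritic cell lists passed (adjusted p = 0.0108, 0.000439, 0.000649 and 0.0292). The interferon and fibroblast lists did not pass fry (adjusted p = 0.0831 and 0.152). Cell cycle genes had 25 of 33 higher (32 adjusted over the list alone), with the mitotic genes Hmmr at 1.27 and Tpx2 at 1.20 (preset adjusted p = 1.08e-13; adjusted p = 0.399 with an estimated correlation). NF-kB response genes had 11 of 18 higher, over all genes and adjusted over the list alone, with the TNF-induced gene Tnfaip2 at 1.59 (preset adjusted p = 4e-07; adjusted p = 0.276 with an estimated correlation). Of 20 neutrophil markers 10 rose, also adjusted over the list alone, with Clec4e, a receptor of activated myeloid cells, at 2.92 (preset adjusted p = 8.76e-05; adjusted p = 0.309 with an estimated correlation). Interferon response genes had 6 of 27 lower, also adjusted over the list alone, with Usp18, which removes ISG15 from proteins, at -1.21 (preset adjusted p = 9.99e-05; adjusted p = 0.504 with an estimated correlation). Dendritic and Langerhans cell markers had 4 of 14 lower, also adjusted over the list alone, with the MHC class II genes H2-Aa at -1.44 and H2-Ab1 at -1.36 (preset adjusted p = 0.00203; adjusted p = 0.474 with an estimated correlation). Fibroblast genes had 6 of 19 lower (7 lower and 1 higher adjusted over the list alone), with the matrix gene Dpt at -0.96 (preset adjusted p = 0.00108; adjusted p = 0.644 with an estimated correlation).

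Part of the muscle and fat markers fell in knockout skin beside these groups. Skeletal muscle markers had 12 of 20 lower and 1 higher (16 and 1 adjusted over the list alone), with Pvalb, the calcium-binding protein of fast fibres, at -2.06 and Actn3, a fast-fibre actinin, at -1.35, and Myh2, a fast myosin, rising by 1.18 (preset adjusted p = 8.31e-06; adjusted p = 0.504 with an estimated correlation). Of 18 adipocyte markers 8 fell (11 adjusted over the list alone), with the fatty acid binding protein gene Fabp4 at -1.38 (preset adjusted p = 9.77e-06; adjusted p = 0.504 with an estimated correlation). The hair list had a median of -2.15, and 0 of 29 members passed limma over all genes or adjusted over the list alone, with 6925 of 22180 genes at an unadjusted p under 0.05 (preset adjusted p = 5.01e-05; adjusted p = 0.669 with an estimated correlation). Chemokines moved both ways, with 10 of 31 higher and 5 lower (10 and 8 adjusted over the list alone), a median of 0.02 and a list adjusted p = 0.369. Sebaceous genes had 4 of 19 higher and 2 lower (6 and 2 adjusted over the list alone), with a list adjusted p = 0.551, and monocyte and macrophage markers 4 of 19 higher (5 higher and 1 lower adjusted over the list alone), with a list adjusted p = 0.188.

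Responses to imiquimod were alike in direction in both genotypes. Of the genes that rose, 1138 were shared, against 159 for independent lists, and of those that fell 739, against 94.1. Arg1 was the 1 gene called in opposite directions. Across genes, which are not independent replicates, the log2 differences in both genotypes correlated at r = 0.835 (Spearman rho 0.656). Of 1878 genes called in both genotypes, 1203 had the larger estimate in knockouts, a comparison of estimates without a test. Xist, which silences 1 X chromosome in females, fell by 0.32 in controls and by 0.63 in knockouts. With the difference of Xist and the mean of the Y-linked genes as a covariate, imiquimod changed 45 genes in controls and 8 in knockouts. That difference was 7.58 ± 0.08 in mock and 7.12 ± 0.16 in imiquimod-treated controls, and 7.65 ± 0.07 and 7.02 ± 0.08 in knockouts (SD, n = 5 each). It shifted with treatment by more than its spread within groups. As a covariate it takes up the treatment difference, so these counts do not show that sex explains the response. The values were high in every group and give no sign of mixed sexes.

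**Figure D2:**
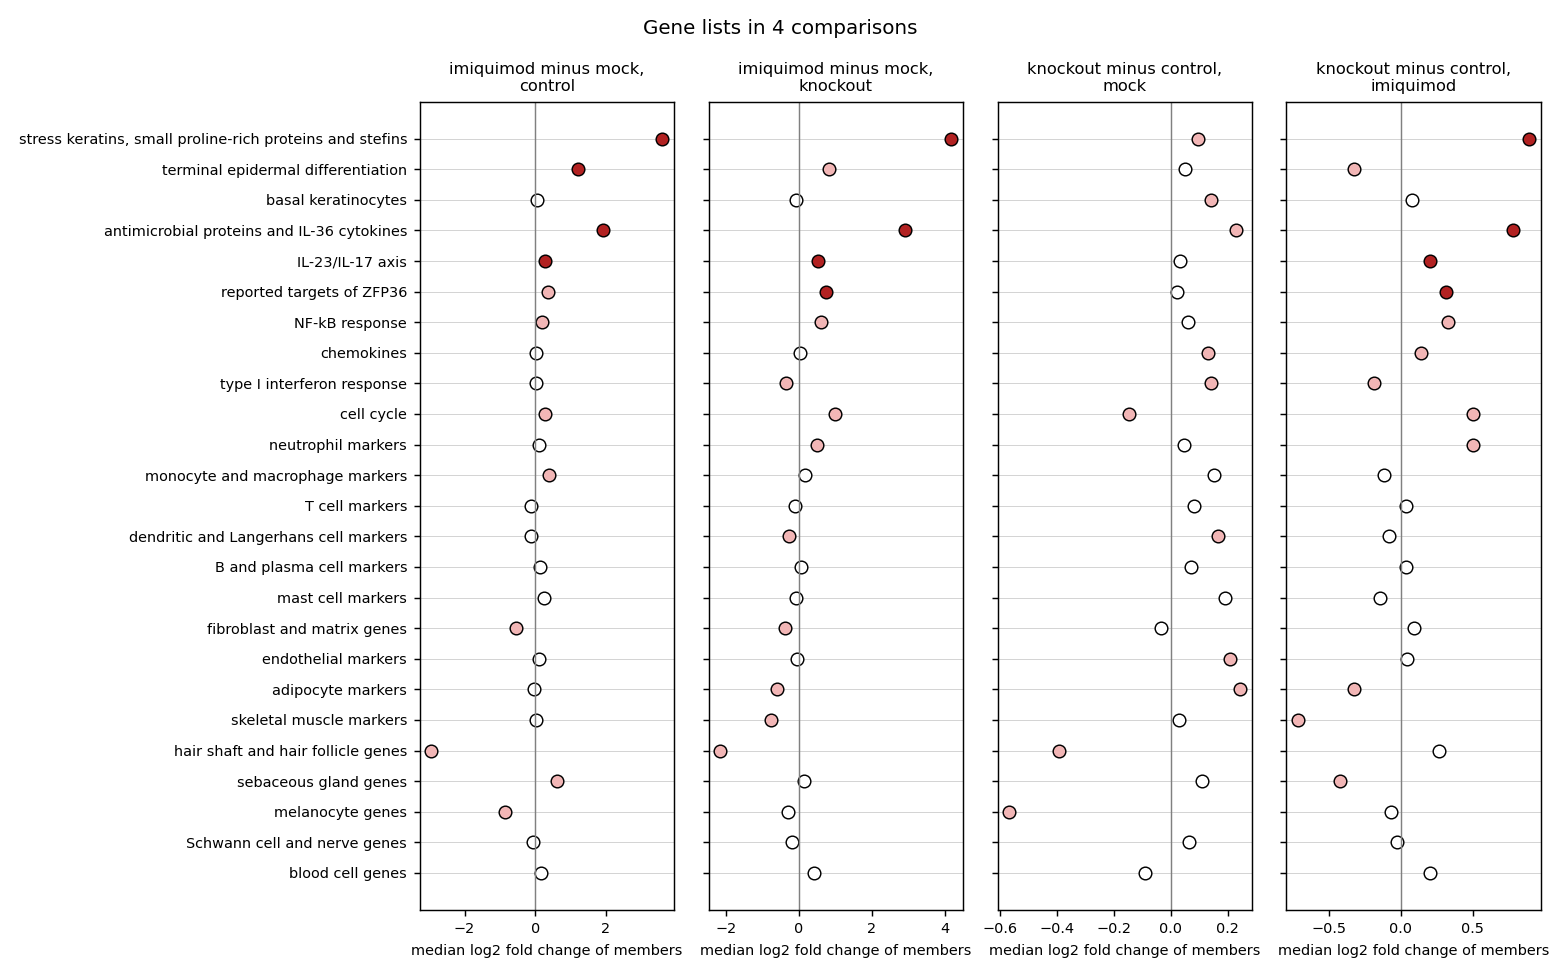
Median log2 difference of each gene list (horizontal axis, with its own range in each panel) for each comparison. Dark red points passed the list test also with an estimated correlation, pale points with the preset correlation alone and white points with neither.

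Without imiquimod, the genotypes differed in few genes. Chil1, a chitinase-like protein gene induced in inflammation, was 2.55-fold higher in mock-treated knockout skin (log2 value 5.74 ± 0.37 in controls and 7.09 ± 0.38 in knockouts, SD, n = 5 each, adjusted p = 0.0164). Aadacl3, an arylacetamide deacetylase-like gene, was higher by 1.21 ± 0.19 (SE, n = 5 per group, adjusted p = 0.0488). No gene was lower, and limma had 708 of 22180 genes at an unadjusted p under 0.05, against 1109 by chance. Serpinb3a lay 1.93 higher (adjusted p = 0.0774) and Krt6b 1.21 higher (adjusted p = 0.999), and Tnf differed by 0.07 (adjusted p = 0.999). In all, 91 genes (0.41%) had the 5 arrays of one genotype all above those of the other, against 0.794% by chance. The count of 2 became 0 without control mock replicate 4 (Chil1 adjusted p = 0.0509) and 4 without knockout mock replicate 5. It was 1 without control mock replicate 1, 2 or 5, control imiquimod replicate 1, 3 or 4, knockout mock replicate 1, 2 or 4, or knockout imiquimod replicate 1, 2, 3 or 5. Aadacl3 kept its call without control mock replicate 3, control imiquimod replicate 5, knockout mock replicate 5 or knockout imiquimod replicate 4, and lost it without any other array (adjusted p from 0.0525 to 0.261).

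Among the lists in mock-treated skin, the antimicrobial and IL-36 group had 1 of 20 members higher, Chil1, over all genes and adjusted over the list alone, with a median of 0.23 (preset adjusted p = 0.00264; adjusted p = 0.475 with an estimated correlation). No reported ZFP36 target passed over all genes in limma, with 708 of 22180 genes at an unadjusted p under 0.05, and 1 was lower adjusted over the list alone, in a list that includes Zfp36 itself. That list had a median of 0.02, a mean of -0.01 and a test that leaned higher (list adjusted p = 0.802). The interferon list had a median of 0.14 (preset adjusted p = 7.18e-05; adjusted p = 0.504 with an estimated correlation), the chemokines of 0.13 (preset adjusted p = 0.000919; adjusted p = 0.311 with an estimated correlation) and the endothelial markers of 0.21 (preset adjusted p = 3.1e-05; adjusted p = 0.482 with an estimated correlation), with no member past the test over all genes or adjusted over the list alone. The endothelial call was lost without knockout mock replicate 3 (adjusted p = 0.072). The stress keratin, basal keratinocyte, cell cycle, dendritic cell, adipocyte, hair and melanocyte lists also passed with the preset correlation and not with an estimated one (adjusted p = 0.504 to 0.819 with an estimated correlation). Each of these calls was lost when certain single arrays were left out, that of basal keratinocyte genes without control mock replicate 1, 2 or 4 or knockout mock replicate 2, and that of hair genes without the same arrays or knockout mock replicate 3, where its median turned to 0.293. With fat genes as a covariate the medians of cell cycle and hair genes turned, to 0.033 and 0.367.

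Under imiquimod the genotypes differed in 121 genes, 83 higher and 38 lower in knockout skin. Il19 was 4.55-fold higher in knockouts, at a log2 value of 6.77 ± 0.66 against 4.58 ± 0.19 in controls (SD, n = 5 each, adjusted p = 2.29e-05). Il1b was 7.10-fold higher (8.86 ± 1.34 against 6.03 ± 0.31, SD, n = 5 each, adjusted p = 0.00186), and Fetub, encoding the protease inhibitor fetuin B, was 4.34-fold higher (7.62 ± 0.43 against 5.50 ± 0.26, SD, n = 5 each, adjusted p = 2.9e-06). Arg1 was 2.08-fold higher (adjusted p = 0.000398). Krt77 was 4.99-fold lower (7.85 ± 0.91 against 10.17 ± 0.50, SD, n = 5 each, adjusted p = 0.00186), and Flg2, encoding a filaggrin-like barrier protein, lay at -2.0 (adjusted p = 0.00245). Of the 121 genes, 44 were at least 2-fold higher and 14 at least 2-fold lower.

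Tnf was 1.62-fold higher in knockout than in control skin under imiquimod (log2 difference 0.70 ± 0.14, SE, n = 5 per group, adjusted p = 0.0286). This call was lost without control imiquimod replicate 1, 2, 4 or 5 (adjusted p = 0.0712, 0.0586, 0.0814 and 0.0865) and without knockout imiquimod replicate 2 or 4 (adjusted p = 0.104 and 0.092). Of 30 reported ZFP36 targets 4 were higher (11 higher and 1 lower adjusted over the list alone), among them Ccl3 at 2.22 (adjusted p = 0.0138). The stress keratin group had 5 of 25 members higher (13 adjusted over the list alone, median 0.89), with Sprr2b, a small proline-rich protein gene, at 2.18. The antimicrobial and IL-36 group had 9 of 20 higher (16 adjusted over the list alone, median 0.78), with Chil3, a chitinase-like protein gene of myeloid cells, at 2.24. Of the IL-23/IL-17 axis 5 of 21 were higher (9 higher and 1 lower adjusted over the list alone). These 4 lists passed with the preset correlation (adjusted p = 3.11e-10, 1.08e-17, 9.47e-20 and 7.41e-09) and with an estimated one (0.0356, 0.0356, 0.00782 and 0.00782). They are not independent: the target list shares Il1b with the IL-23/IL-17 axis and Nos2 with the antimicrobial list, among others. Its rise cannot be told from that of the inflammatory genes in those lists. Muscle markers lay lower in the same arrays, with a median of -0.71.

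Several other lists passed camera between genotypes under imiquimod with the preset correlation and not with an estimated one. Adjusted over the 25 lists of this contrast 13 passed with the preset correlation, against up to 18 in other splits of the arrays. In fry the NF-kB response and neutrophil lists passed (adjusted p = 0.0165 and 0.0202). The chemokine, cell cycle, terminal differentiation and interferon lists did not pass fry (adjusted p = 0.0939, 0.213, 0.152 and 0.397). NF-kB response genes had 4 of 18 higher (8 adjusted over the list alone; preset adjusted p = 2.21e-11; adjusted p = 0.118 with an estimated correlation). Neutrophil markers had 2 of 20 higher (9 adjusted over the list alone), with Clec4e at 2.54 (preset adjusted p = 1.45e-08; adjusted p = 0.109 with an estimated correlation), and their mean log2 value was 6.49 in knockout imiquimod replicate 4 against 5.09 to 5.36 in the other arrays of that group. Chemokines had 1 of 31 higher, Ccl3 (6 higher and 1 lower adjusted over the list alone; preset adjusted p = 0.000762; adjusted p = 0.309 with an estimated correlation). Cell cycle genes had a median of 0.50, with 0 of 33 past limma over all genes or adjusted over the list alone and 2218 of 22180 genes at an unadjusted p under 0.05 (preset adjusted p = 1.84e-11; adjusted p = 0.474 with an estimated correlation). Terminal differentiation genes had 3 of 34 lower, also adjusted over the list alone, Krt77 and Flg2 among them (median -0.33; preset adjusted p = 2.02e-08; adjusted p = 0.343 with an estimated correlation). Type I interferon response genes had a median of -0.18, with 0 of 27 past limma over all genes or adjusted over the list alone (preset adjusted p = 0.00013; adjusted p = 0.504 with an estimated correlation). With the muscle list as a covariate, the medians of the cell cycle, terminal differentiation and interferon lists turned, to -0.082, 0.097 and 0.042. The monocyte and macrophage list had 1 of 19 higher, Arg1, also adjusted over the list alone, with a median of -0.11, a mean of 0.02 and a list test that leaned lower (adjusted p = 0.894); with the muscle list as a covariate its median was 0.352.

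The muscle, fat and sebaceous lists had medians below 0 between genotypes under imiquimod. Each passed camera with the preset correlation and not with an estimated one. In fry the muscle list passed (adjusted p = 0.0287), and the adipocyte and sebaceous lists did not (adjusted p = 0.468 and 0.0905). Skeletal muscle markers had 2 of 20 lower (17 adjusted over the list alone), with a median of -0.71 (preset adjusted p = 7.57e-20; adjusted p = 0.118 with an estimated correlation). The 2 were the fast myosin gene Myh4 and Mybpc2, a myosin-binding protein gene. Myh4 lost its call without control imiquimod replicate 1, 2 or 4 or knockout imiquimod replicate 1, 2 or 4 (adjusted p from 0.0623 to 0.103). Mybpc2 kept its call without control mock replicate 5, control imiquimod replicate 5, knockout mock replicate 3 or knockout imiquimod replicate 5, and lost it without any other array (adjusted p from 0.0513 to 0.157). The muscle kinase gene Mylk4, outside that list, lay at -1.72 (adjusted p = 0.0117). Sebaceous genes had a median of -0.42, with 0 of 19 past limma over all genes and 2 lower adjusted over the list alone (preset adjusted p = 2.7e-06; adjusted p = 0.194 with an estimated correlation). Adipocyte markers had a median of -0.33, with 0 of 18 past either adjustment, also adjusted over the list alone (preset adjusted p = 0.000225; adjusted p = 0.584 with an estimated correlation), and their median was 0.222 with the muscle list as a covariate. Skin-specific Skint6, related to a gene needed for epidermal gamma-delta T cells, lay at -1.80 (adjusted p = 0.00978). With the muscle list as a covariate 44 genes passed, 26 of them shared with the 121, and none of the 38 lower genes, Krt77, Flg2, Mylk4 and Skint6 included, was called. The 83 higher genes kept a median of 98% of their log2 difference (1.04 before, 0.98 with the covariate) and the 38 lower genes 59.1% (-0.70 and -0.44), while the median standard error of the 121 went from 0.175 to 0.201.

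The count of 121 moved with single arrays, between 45 and 174. It was 65, 45, 62 and 63 without control imiquimod replicate 1, 2, 4 and 5, and 72, 47 and 56 without knockout imiquimod replicate 1, 2 and 4; it was higher without control mock replicate 5 (141), control imiquimod replicate 3 (161), knockout mock replicate 3 (140) or knockout imiquimod replicate 3 or 5 (145 and 174). Without the 4 arrays apart in hair genes, an alternative chosen after seeing the data, 54 genes passed, 42 of them among the 121. Of 27 named genes past the threshold, 15 kept their call whichever array was left out, Il19, Il1b, Fetub, Arg1, Krt77, Flg2, Sprr2b, Chil3, Ccl3 and Clec4e among them, and 12 lost it without at least 1 array: Tnf, Csta3, Skint9, Mstn, Lce1m, Skint5, Mrgprb3, Myh4, Saa3, Tnfaip2, Clec4d and Mybpc2. In all, 548 genes (2.47%) had the 5 arrays of one genotype all above those of the other, against 0.794% by chance. The count of genes past the threshold was 17 when the fit held the groups of this contrast alone and 242 with array weights. With the hair list as a covariate that count was 345, 156 higher and 189 lower, which kept all 121. Across genes, the genotype differences under mock and imiquimod had a correlation of r = -0.031 (Spearman rho -0.031). Its jackknife SE from leaving out each array was 0.321, so it does not show that the 2 differences are unrelated.

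The genotype difference under imiquimod was also set against the imiquimod response of controls, which share the control imiquimod arrays with opposite sign. Of the genes higher in knockouts 46 had also risen in controls, against 5.37 for independent lists, and 5 had fallen; of the lower genes 9 had fallen, against 1.66, and 2 had risen. The correlation across genes was 0.0372 with all arrays in both comparisons and 0.123 on average with the shared arrays split (20 splits, from -0.181 to 0.463), beside -0.502 simulated without effects. The covariance was 0.0033 unsplit and 0.0151 split, beside a simulated -0.0144.

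A test of the difference in response asked which genes answered imiquimod differently in knockout and control skin. It called 4 genes, each with a higher response in knockouts, out of 1497 at an unadjusted p under 0.05. Fetub responded more by 2.07 ± 0.25 and Il19 by 2.25 ± 0.32 on the log2 scale (SE, n = 5 per group, adjusted p = 0.000723 and 0.00549). Arg1 fell by 1.05 in controls and rose by 0.55 in knockouts, a difference in response of 1.60 ± 0.19 (SE, n = 5 per group, adjusted p = 0.000723). Cdhr1, a cadherin-related gene known from photoreceptors, had a difference of 1.01 ± 0.15 (SE, n = 5 per group, adjusted p = 0.00549). Other genes with sizeable differences did not pass, among them Il1b at 2.29 (adjusted p = 0.333), Ccl3 at 2.40 (adjusted p = 0.328), Krt77 at -2.28 (adjusted p = 0.186) and Tnf at 0.63 (adjusted p = 0.581). Without knockout imiquimod replicate 3 the count was 8, and without knockout imiquimod replicate 4 it was 7; with the hair list as a covariate it was 12.

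For responses, 13 lists passed with the preset correlation and 0 with an estimated one. The antimicrobial and IL-36 list had a median difference in response of 0.48, with 0 of 20 members past limma over all genes and 9 higher adjusted over the list alone (preset adjusted p = 1.45e-08; adjusted p = 0.107 with an estimated correlation). The IL-23/IL-17 axis had 1 of 21 higher, Il19 (5 higher and 1 lower adjusted over the list alone; preset adjusted p = 6.51e-05; adjusted p = 0.0691 with an estimated correlation). Reported ZFP36 targets had a median of 0.21, with 0 of 30 over all genes and 8 adjusted over the list alone (preset adjusted p = 3.3e-07; adjusted p = 0.0976 with an estimated correlation). Muscle markers had a median of -0.77, with 0 of 20 over all genes and 10 lower adjusted over the list alone (preset adjusted p = 1.1e-13; adjusted p = 0.22 with an estimated correlation).

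**Figure D3:**
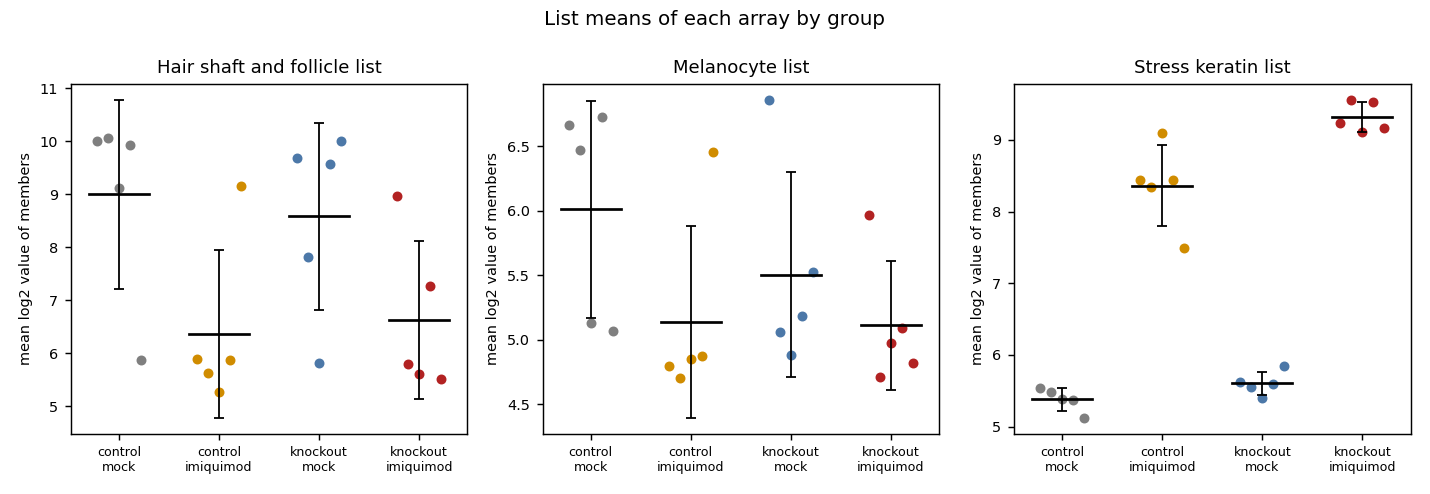
Mean log2 value (vertical axis) of selected gene lists in each of the 20 arrays by group. Hair genes lie at 5.87 in control mock replicate 5 and at 9.16 in control imiquimod replicate 5, each apart from the other arrays of its group.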

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

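Among the tests reported here, those of hair cycle stage and muscle share on the genotype difference, of dilution by a thicker epidermis and of exchanged treatment labels, and the fit without 4 arrays apart in hair genes, were chosen after the result was seen.

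The first pattern is the genotype difference under imiquimod. Of 100 splits of the arrays the others gave at most 15 genes, against the real 121, so chance is an unlikely source of that count. It was 17 in the fit of its own groups alone and 45 to 174 without 1 array, and splits of those fits were not counted. With the hair list as a covariate, the 121 genes kept a median of 99.8% of their log2 difference and all 121 stayed past the threshold. The hair list means under imiquimod were close, 6.36 ± 1.58 in controls and 6.63 ± 1.49 in knockouts (SD, n = 5 each). That covariate could thus shift the differences little, and the closeness itself argues against hair cycle stage as the whole source. Without the 4 arrays apart in hair genes, a fit of fewer arrays, 54 genes passed. A smaller share of muscle in the knockout samples would raise all other genes alike and lower no epidermal ones. Basal keratinocyte genes had a median of 0.08 (SE 0.141, 12 genes, mean -0.04) against 1.036 for the 83 higher genes. The 83 were picked as higher in this same contrast, so that gap was partly set by the choice and cannot decide. With the muscle list as a covariate, the 83 kept a median of 98% of their log2 difference (1.036 before, 0.979 after). Of the 83, 26 stayed past the threshold, and the median SE of the 121 went from 0.175 to 0.201. The terminal differentiation list, to which the lower genes Flg2, Krt77 and Lce1m belong, had a median of -0.327 (SE 0.147, 30 of 34 below 0). It was 0.097 with the muscle list as a covariate. The difference kept by the 83 higher genes argues against a smaller muscle share as their whole source. The fall of the terminal differentiation list cannot decide for these 3 lower genes. They belong to that list, and its median turned with the muscle list as a covariate. Its SE also treats genes that move together as independent. The median of the 3 went with that covariate from -2.004 (median SE 0.332) to -1.19 (0.284), and their calls ended as the difference shrank. For the other 35 lower genes a lower muscle share and a genotype or litter effect cannot be told apart, since the muscle list itself differed between the groups (with that list as a covariate a median of 58.8% was kept, from -0.67 to -0.43, the median SE went from 0.136 to 0.15, and 0 stayed past the threshold), and for all 121 a genotype or litter effect stays open, as a hypothesis.

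The second pattern is that of 4 arrays, the farthest from its group's median in each group, whose hair genes lay near the level of the other treatment: control mock replicate 5, control imiquimod replicate 5, knockout mock replicate 3 and knockout imiquimod replicate 1. Exchanged treatment labels would move the imiquimod-responsive genes too, but 4 of the 4 arrays had a stress keratin list mean on the side of their own treatment (5.12, 7.5, 5.40 and 9.24), though the 7.5 lay below the 8.34 to 9.09 of its group. Hair cycle stage may differ between the animals: within groups, melanocyte genes, which are expressed in growing follicles, followed hair genes across the 20 arrays at r = 0.789 (Spearman rho 0.762, permutation p = 7e-05 and 0.00013, adjusted over 4 relations 0.00028 and 0.00052). Without control imiquimod replicate 5 and control mock replicate 5, the 2 farthest arrays, r was 0.694. No record of hair cycle stage was used here, and what set the stage was not tested.

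The third pattern is that skeletal muscle genes lay lower in imiquimod-treated knockout skin, with a median of -0.71 and 20 of 20 below 0. Of these 2 passed over all genes, and the list did not pass camera with an estimated correlation (adjusted p = 0.118). A candidate explanation is the depth of the sampled skin, since the muscle layer and fat lie below the dermis. Within groups, muscle and adipocyte genes moved together across the 20 arrays at r = 0.688 (Spearman rho 0.647, permutation p = 0.00194 and 0.00733, adjusted over 4 relations 0.00388 and 0.0147). Without control mock replicate 5 and knockout mock replicate 3, the 2 farthest arrays, r was 0.55. Both are among the 4 arrays apart in hair genes. With the muscle list as a covariate the hair list's median in this contrast went from 0.27 to -2.75. The muscle list thus also carried variation that goes with hair genes, and this r cannot tell depth from it. Dilution by a thicker epidermis would lower dermal genes alike, but the fibroblast and endothelial lists together had a median of 0.058 (35 genes) against -0.712 for muscle (20 genes). Their SEs of 0.036 and 0.093 treat genes that move together as independent. By array, fibroblast list means under imiquimod were 8.42 ± 0.06 in controls and 8.47 ± 0.20 in knockouts, and endothelial means 6.04 ± 0.18 and 6.10 ± 0.13. Muscle means were 8.75 ± 0.36 and 7.95 ± 0.31 (SD, n = 5 each). This argues against dilution as the whole source. A change in muscle expression stays open and was not tested.

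Other splits of the arrays were counted for each result, 100 of them each. For imiquimod in controls the real count of 2404 genes stood against at most 719, and in knockouts 4605 against at most 1281. In both, 1 of 100 splits, the real one, gave as many, so chance is an unlikely source of these counts. The difference in responses had 4 against at most 1, and again 1 of 100 splits, the real one, gave as many. There the genotype labels were exchanged within each treatment, which asks about any genotype difference rather than the response alone. Its count therefore does not exclude chance for the difference in responses. For genotype in mock-treated skin, 6 splits, the real one included, gave 2 genes or more and 1 gave 1414, so chance cannot be excluded for the real 2, and a split that called so many times more genes points to a structure of the samples. For the numbers of lists past the preset test, adjusted over the 25 lists of a contrast, chance could not be excluded: 39 splits, the real one included here and in the next counts, gave the real 12 lists or more for imiquimod in controls (highest other 22), 36 gave 14 or more for imiquimod in knockouts (19), 44 gave 10 or more for genotype in mock-treated skin (18), 27 gave 13 or more for genotype under imiquimod (18) and 20 gave 13 or more for the responses (21).

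Single arrays lay far from the other 4 of their group in 25 of 416 groups of named gene values and in 11 of 100 groups of list means, where chance gives about 1 in 20 (20.8 and 5). Control imiquimod replicate 5 held 12 of these log2 values: it was low in Aadacl3 (8.66), Il1f6 (10), Sprr2e (6.64), and the basal keratinocyte (8.16), chemokine (5.47), dendritic cell (5.48) and endothelial (5.73) lists, and high in Cxcl14 (8.90), Krt81 (8.69), Mitf (7.80), and the hair (9.16) and melanocyte (6.46) lists. Control mock replicate 5 was low in Hoxc13 (5.38), Krt81 (6.03), Mitf (7.18) and the hair list (5.87), and high in Sprr2b (6.04) and the B and plasma cell list (4.51). Knockout mock replicate 1 was high in Chil1 (7.76) and low in Ier3 (7.45), the NF-kB response list (6.11) and the blood cell list (4.67), and knockout mock replicate 3 was high in Eng (6.91) and Tshr (6.70) and low in Zfp36l1 (8.76). Knockout imiquimod replicate 4 was high in Cd14 (8.69) and the neutrophil list (6.49) and low in Myh4 (8.63). Among other arrays, control mock replicate 3 was high in Ier3 (7.99), control mock replicate 4 in Cxcr2 (5.79), control imiquimod replicate 1 in Fabp4 (10.58) and Ltf (6.42), control imiquimod replicate 3 in Cdhr1 (5.14), control imiquimod replicate 4 in Mcm4 (7.43), knockout mock replicate 5 in S100a8 (6.30) and knockout imiquimod replicate 5 in Retnla (5.01).

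The response to imiquimod differed between genotypes, by the test of the difference itself, in Arg1 (1.60), Cdhr1 (1.01), Fetub (2.07) and Il19 (2.25). Camera with the preset correlation also called lists, given here with the median difference in response of their members, which camera does not itself test. Higher were stress keratins (0.53), antimicrobial and IL-36 (0.48), IL-23/IL-17 axis (0.18), ZFP36 targets (0.21), NF-kB response (0.25), cell cycle (0.66) and neutrophils (0.57). Lower were terminal differentiation (-0.47), interferon response (-0.36), dendritic cells (-0.18), adipocytes (-0.57), muscle (-0.77) and sebaceous gland (-0.58). None of these lists passed with an estimated correlation. Among the 17824 probe sets without a single gene name, imiquimod changed 586 in controls (346 higher, 240 lower) and 1244 in knockouts (541 higher, 703 lower).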

How the results depend on the processing

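The fit without 4 arrays apart in hair genes was chosen after the result was seen. Of the named genes' values, 3335 of 3520 kept direction and side of the threshold when 1 array was left out, with 167 weaker, 18 stronger and 0 reversed; of 2442 values under other settings, 2199 did, with 218 weaker, 23 stronger and 2 reversed. No detection calls were used, so the signal over background limits the reading of dim genes.

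Imiquimod in controls (2404 genes) gave 3697 with array weights and 45 with the sex-linked covariate, and 1619 to 2989 without 1 array; imiquimod in knockouts (4605) gave 8 with the sex-linked covariate and 3654 to 4952 without 1 array. Genotype in mock (2) gave 0 with its own groups alone, 4 with array weights or the muscle covariate, 1 with median centring, the fat or sex-linked covariate or without the 4 arrays, 7 probe sets, 5 with the hair covariate, and 0 to 4 without 1 array. Genotype under imiquimod (121) gave 17 with its own groups alone, 242 with array weights, 67 probe sets, 345 with the hair, 44 with the muscle and 71 with the sex-linked covariate, 54 without the 4 arrays, and 45 to 174 without 1 array. The responses (4) gave 8 with array weights, 12 with the hair and 7 with the muscle covariate, and 4 to 8 without 1 array. Lists past the test (63) were 12 with an estimated correlation, 25 with fry, and 56 to 75 without 1 array. The cause was not tested beyond the fewer samples of an own-groups fit. The sex-linked covariate itself moved with treatment, so it takes up the treatment difference in its imiquimod counts.

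The similarity of both responses was 0.784 to 0.875 and that of both genotype differences -0.147 to 0.127 without 1 array. The jackknife SEs from leaving out each array were 0.109 and 0.321, so the second correlation is known only loosely. Zfp36 differed by -2.45 to -1.54 in mock and -1.85 to -1.37 under imiquimod without 1 array. Its response was 0.44 to 0.62 in controls, with 0.54 past the threshold in the fit of its own groups (adjusted p = 0.033; 0.033 to 0.999 over settings), 0.48 to 1.39 in knockouts, with 1.39 past it without knockout mock replicate 3 (adjusted p = 0.0432) and 1.62 past it without the 4 arrays (adjusted p = 0.0246; 0.0246 to 0.845), and the difference in response -0.06 to 0.85.

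The direction of a list's test turned under these covariates, given with the list's median there, the cause not tested. With hair genes: imiquimod in controls, monocytes -0.041, endothelium -0.19, muscle -0.47. With muscle genes: imiquimod in knockouts, endothelium 0.23; genotype under imiquimod, terminal differentiation 0.10, interferon 0.042, cell cycle -0.082, monocytes 0.35, dendritic cells 0.22, adipocytes 0.22, hair -2.75; responses, terminal differentiation 0.093, monocytes 0.28, T cells 0.14, dendritic cells 0.05, endothelium 0.17, hair -2.31, melanocytes -0.64. With fat genes: imiquimod in knockouts, endothelium 0.27; genotype in mock, terminal differentiation -0.093, cell cycle 0.03, fibroblasts -0.15, hair 0.37; genotype under imiquimod, hair -0.69; responses, endothelium 0.12, hair -1.16. Fibroblasts in mock had a median below 0 (-0.03) before as well. Without 1 array, the test's direction for genotype in mock turned for muscle (median 0.225 without control mock replicate 5, 0.03 with all arrays, range -0.109 to 0.225), adipocytes (0.046 without knockout mock replicate 3, range 0.046 to 0.356) and hair (0.293 without knockout mock replicate 3, range -1.285 to 0.293). With the sex-linked covariate, Cxcl14 (0.10) and Mitf (0.082) turned in knockouts under imiquimod.

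The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at a mean of -0.0147 (-0.709 to 0.516, 14 of 30 pairs over 0.1), and 2 of 20 arrays correlated best with an array of their own number. With the replicate block, imiquimod changed 2036 genes in controls and 4230 in knockouts, genotype 3 in mock and 78 under imiquimod, and 4 genes differed in response, with 63 lists past the test.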

Other observations

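The relations of Zfp36 signal with gene lists were planned before their results were seen, and no test in this part was chosen afterwards.

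Among immune lists outside the comparisons above, single T and mast cell genes moved both ways and no list passed the preset test with imiquimod. T cell markers had 1 of 15 higher in controls with imiquimod, Cd5, encoding a T cell surface receptor, at 0.26 (adjusted p = 0.0489; 0 adjusted over the list alone; list adjusted p = 0.234). Cd5 kept that call without control mock replicate 4 or 5, knockout mock replicate 3 or 5 or knockout imiquimod replicate 3, and lost it without any other array (adjusted p from 0.0503 to 0.136). In knockouts 1 was higher, Cd5, at 0.32, and 2 lower, the T cell receptor complex genes Cd3g at -1.34 and Cd3e at -0.78 (1 and 2 adjusted over the list alone; list adjusted p = 0.227). Mast cell markers in knockouts had 1 of 12 higher, Hdc, the histamine-forming enzyme, at 1.22, and 2 lower, the mast cell receptor genes Mrgprb2 at -0.99 and Kit at -0.92 (the same numbers adjusted over the list alone; list adjusted p = 0.685). B and plasma cell markers had 0 of 10 past limma with imiquimod in controls or knockouts, over all genes or adjusted over the list alone, with 5300 and 6925 of 22180 genes at an unadjusted p under 0.05 (list adjusted p = 0.585 and 0.723).

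Basal keratinocyte genes in knockouts moved both ways, with 4 of 12 higher and 4 lower, also adjusted over the list alone. Krt14 rose by 1.27 and Itga6, a hemidesmosome integrin, by 0.62, while Krt15 fell by 2.25 (list adjusted p = 0.894). Endothelial markers in knockouts had 1 of 16 higher, the co-receptor gene Eng, at 0.38, and 1 lower, the receptor gene Tek, at -0.78 (the same numbers adjusted over the list alone; median -0.04; list adjusted p = 0.919; median 0.231 with muscle genes as a covariate). Eng lost its call without knockout mock replicate 1, 2, 4 or 5 or knockout imiquimod replicate 2 or 4 (adjusted p from 0.0502 to 0.0705). Melanocyte genes had 2 of 10 lower in knockouts, with Mitf at -1.19 (0.082 with sex-linked genes as a covariate), also adjusted over the list alone (list adjusted p = 0.121). Schwann cell genes had 1 of 9 lower there, Egr2, a regulator of myelination, at -0.48. Of 12 blood cell genes 3 were measured, and none passed limma over all genes in any contrast (list adjusted p = 0.509 with imiquimod in knockouts, where 1 was higher adjusted over the list alone).

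Zfp36 signal left in the knockout arrays ranged widely, which raised the question of whether it tracked the inflammatory genes. If loss of Zfp36 in each sample set the level of the antimicrobial and IL-36 genes, arrays with more Zfp36 left would have had less of them. Across the 10 knockout arrays, within groups, r was 0.307 (Spearman rho 0.152, permutation p = 0.267 and 0.649, two-sided, r = 0.437 without knockout mock replicates 3 and 2). Skin cells other than keratinocytes keep the gene, and whether the probes lie within the floxed part is unknown. The signal may thus not measure loss in keratinocytes, and this r cannot decide the question. Zfp36 signal may also follow hair cycle stage, since it fell as hair genes rose: r = -0.694 (Spearman rho -0.697, permutation p = 0.0492 and 0.0339, adjusted over 4 relations 0.0657 and 0.0452). The Pearson value failed the adjustment, and r was -0.487 without knockout mock replicates 3 and 2, so the relation leans on those arrays.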
